A study of Mus musculus with 8 samples.

How the data were processed

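Gene expression was measured by RNA sequencing in 8 samples labelled as primary mouse renal fibroblasts. Of these, 4 were infected with an adenovirus carrying GFP (Ad-GFP) and 4 with an adenovirus carrying Cre recombinase (Ad-Cre). Per the labels' protocols, all samples received TGF-β at 5 ng/ml for 48 hours and RNA was extracted with Trizol. The labels give the Ad-GFP samples as wild type and the Ad-Cre samples as having Suv39h1 knocked down. No label says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

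The deposited table holds 22322 Ensembl genes. The deposited counts are whole-number read counts per gene, per the file headers, and the authors also deposited FPKM values of the same libraries and the mean FPKM of each group. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. The gene length implied by a count and its FPKM was computed for the 3673 genes with over 1000 counts in every library, and it varied between libraries by a coefficient of variation over 1% for 1758 of them, so the counts may be rounded estimates. The authors' deposited log2 fold change equals the log2 ratio of their group mean FPKM, as checked on the table. The authors' deposited p-values have no named test, and their FDR equals a Benjamini-Hochberg adjustment over the rows with a p-value below 1. KEGG and Gene Ontology terms are those the table carries. Gene coordinates came from GENCODE M21 on GRCm38, in which 22267 of the 22322 gene IDs were found.

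Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr, which kept 13337, libraries were scaled with TMM factors (0.992 to 1.01), and Ad-Cre was compared with Ad-GFP by the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is said to rise, fall or change only where it passed this threshold. Standard errors are the absolute log2 fold change divided by the square root of F, and the 95% interval of the Suv39h1 ratio uses the fit's 25.2 degrees of freedom. CPM values are counts relative to the TMM-scaled library totals, and SDs are over the 4 libraries of a group. The design was not blocked, because the labels state no pairing.

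Before the data were examined, 34 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2. The 32 lists with at least 5 tested members entered, with adjustment over the lists. Camera with a correlation estimated from the residuals and fry were run beside it. Annotation terms with 10 to 500 tested genes were tested for enrichment among genes called higher and among genes called lower by a 1-sided Fisher's exact test (scipy 1.17.1), against tested genes carrying any term of that kind, with adjustment over terms and directions within each kind. The terms printed are among the 3 of smallest p per kind and direction.

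The naming rule always takes Suv39h1, Suv39h2, Acta2, Tagln, Col1a1, Col1a2, Col3a1, Fn1, Postn and Ccn2. It adds the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap. It takes the 3 members of smallest p from each pathway list called by camera, and the called member of smallest p from each other pathway list. From each cell type or quality list it takes the 2 members of highest CPM, and from each printed term up to 3 called members of smallest p. Of the genes the rule takes, 2 are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

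The alternatives were other scaling factors (RLE, upper quartile), no filter, a filter of at least 5 CPM, DESeq2 1.42.0, limma-voom with and without quality weights, the replicate number as a block, leaving out each library in turn, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1. Thinning every library to the smallest library total of 15879244 counts was added after the library totals were seen. The fit was tested on simulated data made from these libraries' means and totals, with 200 of 13337 genes changed. For Ad-Cre against Ad-GFP, it recovered 73.1% of the genes changed 1.25-fold, 83.6% of those changed 1.5-fold and 95.5% of those changed 2-fold, and 6.67% of its calls were unchanged genes. Camera called the simulated list of changed genes and 0 of 20 simulated unchanged lists. The simulation drew each gene independently, so it cannot show how often camera calls unchanged lists of correlated genes. It changed few genes, as many up as down, so it cannot test the scaling or the share of false calls where many genes change. In a test on simulated calls, the enrichment step recovered the planted KEGG term and called 1 other of the 314 terms. Those calls too were drawn independently per gene, so they cannot show how often terms of correlated genes are called.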

Results

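Transcriptomes were profiled in 8 samples labelled as primary fibroblasts from mouse kidney, all stimulated with TGF-β, 4 after infection with Ad-GFP and 4 after infection with Ad-Cre, to ask how depletion of the H3K9 methyltransferase Suv39h1 alters expression in these samples. TGF-β drives fibroblasts toward contractile, matrix-producing myofibroblasts. All samples were treated with TGF-β, so no unstimulated baseline enters the comparison. The Ad-GFP libraries held 17351279, 17930632, 16810925 and 15879244 counts and the Ad-Cre libraries 18006938, 23940043, 20990346 and 22249570, so every Ad-Cre library was deeper than every Ad-GFP library. Mitochondrially encoded genes took 7.59% to 8.0% of the counts of a library. The first principal component carried 51.7% of the variance and separated the groups. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.83 to 3.35. The fit's common biological coefficient of variation was still low, at 2.89%, so small differences between the groups could be called.

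Suv39h1 (ENSMUSG00000039231), on the minus strand of the X chromosome at 8061171 to 8074760 (GRCm38), was lower in Ad-Cre but far from absent. It was at 28.96, 27.82, 29.32 and 29.58 CPM in Ad-GFP replicates 1 to 4 and at 25.29, 22.75, 21.63 and 22.56 CPM in Ad-Cre replicates 1 to 4, and the groups did not overlap. The Ad-Cre level was 79.6% of Ad-GFP (95% interval 73.5% to 86.2%), a log2 fold change of -0.33 ± 0.056 (SE, n = 4 per group), with an adjusted p = 3.293e-05 by edgeR's quasi-likelihood test. The exact permutation test of its CPM gave p = 0.0286, two-sided, the smallest that 4 against 4 samples allow. The table gives a total per gene, so counts from exons inside and outside any deleted part were not told apart. Its exons also overlap an antisense gene, Gm14820, over 767 bases, and whether reads were assigned by strand is not given in the sources used here. The paralog Suv39h2 was at 7.82 ± 0.21 CPM in Ad-GFP and 8.07 ± 0.59 CPM in Ad-Cre (SD, n = 4; adjusted p = 0.768).

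**Figure D1:**
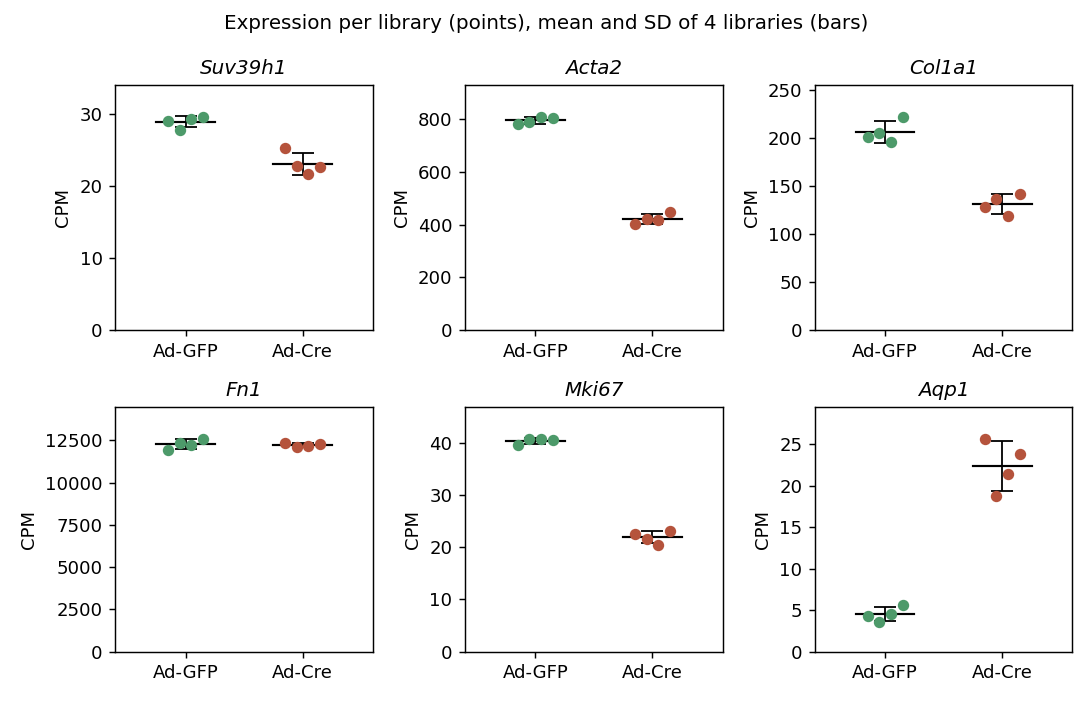
Normalised expression (CPM, linear axes from 0) of 6 genes in each library, with the mean and SD of 4 libraries per group as black bars. Suv39h1, Acta2, Col1a1 and Mki67 lie lower in every Ad-Cre library than in any Ad-GFP library, Aqp1 lies higher, and Fn1 overlaps between the groups.

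Of 27 tested contractile and myofibroblast genes, 18 fell and 5 rose in Ad-Cre, while the fibronectin gene Fn1 was near its Ad-GFP level. Camera called that list (adjusted p = 8.176e-10), but not with an estimated correlation (adjusted p = 0.0696). Acta2, which encodes the α-smooth muscle actin of myofibroblasts, dropped from 796.3 ± 12.8 to 422.1 ± 18.9 CPM (SD, n = 4), 53.04% of Ad-GFP (adjusted p = 1.316e-19). Its locus is on chromosome 19 at 34241090 to 34255590. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 were at 63.7%, 66.9% and 79.8% of their Ad-GFP level, with adjusted p-values of 1.26e-12, 2.004e-12 and 6.299e-05. In contrast, Fn1 was at 12270 ± 284 CPM in Ad-GFP and 12220 ± 102 CPM in Ad-Cre (SD, n = 4), 99.6% of Ad-GFP (adjusted p = 0.783). Ccn2 fell to 91.4%. The labels name the cells as fibroblasts, but epithelial transcripts were abundant as well (Krt8 at 1504 CPM in Ad-GFP). Mural cell markers (4 of 6; camera adjusted p = 0.0227, and 0.132 with an estimated correlation) and endothelial markers (14 of 15) also fell. The mural falls include Des and Myh11, named after their values were seen, which are also on the contractile list. The mural list is therefore not separate evidence. Which cells the contractile and matrix transcripts came from was not determined here.

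Over all genes tested, 5370 of 13337 changed, 2641 higher and 2729 lower in Ad-Cre. That near-even split depends on the processing. Upper-quartile factors gave 2164 higher and 3089 lower, and limma on log2(FPKM + 1) gave 1400 and 2130. Most changes were small: 256 genes changed at least 2-fold, and of these 239 were lower and 17 higher. Of the 256, 189 of the falls and 13 of the rises had a mean under 5 CPM. The 2-fold count depends on such genes, as a filter of at least 5 CPM left 56. Limma on log2(FPKM + 1), which differs in unit, test, filter and pseudocount, gave 3530 changed genes and 28 changed at least 2-fold. In 35.4% of the genes the groups did not overlap, against 2.86% by chance for 4 against 4. The authors' deposited table holds 4167 genes at an FDR under 0.05, 326 of them at least 2-fold. Of the 4167 genes called in the authors' deposited table, 4097 were also called here, 4071 of them with the same sign.

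The largest falls among genes of at least 5 CPM were in Spink12, Acta1, Pycard, Cyp4b1, Haus8 and Ceacam1. Spink12, of the Kazal-type serine protease inhibitor family, fell from 46.3 ± 3.3 to 8.97 ± 0.63 CPM (SD, n = 4). Acta1, the skeletal muscle α-actin gene, was at 25.1% of Ad-GFP (182.9 ± 9.1 against 45.7 ± 3.6 CPM). Pycard, the inflammasome adaptor ASC, was at 28.8%, Cyp4b1 at 30.7%, Haus8, a subunit of the augmin complex of the spindle, at 31.3%, and the adhesion molecule gene Ceacam1 at 32.3%. The largest rises were in Aqp1, Aoc1, Slc34a2, Ifit3b, Ifit3 and Gpx3. The water channel gene Aqp1 rose from 4.52 ± 0.86 to 22.4 ± 3.0 CPM. Aoc1, a diamine oxidase, was at 247.3% of Ad-GFP, the phosphate transporter gene Slc34a2 at 234.3%, and the secreted glutathione peroxidase gene Gpx3 at 188.3%. All 12 passed edgeR's test, with adjusted p-values from 4.883e-22 for Acta1 to 4.909e-09 for Aoc1. The actin genes share long stretches of sequence, as do Ifit3 and Ifit3b and the H2-Q6 and H2-Q7 genes, so the split of reads between these copies is uncertain. Exons of Haus8 overlap those of Myo9b on the other strand over 116 bases. Among genes named elsewhere, longer overlaps of this kind include Csf1r with Hmgxb3 (873 bases), Fdft1 with Ctsb (774) and Pfkp with Pitrm1 (748). Suv39h2 with Dclre1c (357) and Ucp2 with Dnajb13 (305) overlap too. Whether reads were assigned by strand is not given, so counts of these genes may include reads of the other gene.

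Of the 32 gene lists tested, camera called 15, 12 lower and 3 higher in Ad-Cre. With a correlation estimated from the residuals, 4 were called, all lower: mitosis, DNA replication, antigen presentation and endothelial markers. The contractile and myofibroblast cytoskeleton list had 19 falls and 5 rises when adjusted over the list alone, against 18 and 5 over all genes tested, and a median log2 fold change of -0.29. Acta2, the regulatory light chain gene Myl9 (50.7% of Ad-GFP) and the calponin gene Cnn1 (52.6%) had its smallest p-values, and Tagln, encoding transgelin, was at 72.6%.

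Of the 44 fibrillar collagen and matrix genes, 24 fell and 4 rose (26 and 4 when adjusted over the list alone), with a median log2 fold change of -0.26 (camera adjusted p = 6.927e-06; adjusted p = 0.171 with an estimated correlation). Members did not move as a block. The 3 members of smallest p all rose: the thrombospondin gene Thbs1 to 132.6%, Fbln2 to 130.8% and Col18a1 to 131.3% of Ad-GFP. Postn fell to 84.5%. Among 25 collagen processing genes 7 fell and 3 rose, and the lysyl oxidase family gene Loxl4 fell to 54.6%, with a camera adjusted p = 0.374 for the list. Among 26 matrix proteases and inhibitors 10 fell and 7 rose (camera adjusted p = 0.641), and Serpine2 fell to 61.6%.

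TGF-β early targets and feedback genes went both ways. Of 32 tested, 10 rose and 11 fell (11 and 12 when adjusted over the list alone), with a median log2 fold change of -0.02 (camera adjusted p = 0.802). Fry called the list lower (adjusted p = 0.0329). Inhba, encoding an activin subunit, fell to 63.9%. The BMP response list (3 rose and 5 fell of 18; Bmpr2 rose to 118.3%) had a camera adjusted p = 0.802. The YAP and TEAD target list (7 rose and 5 fell of 24; Igfbp3 fell to 45.3%) had a camera adjusted p = 0.618.

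Proliferation genes fell together. Of 36 mitosis genes 34 fell and 0 rose (35 and 0 when adjusted over the list alone), with a median log2 fold change of -0.78 (camera adjusted p = 5.401e-16; adjusted p = 0.00717 with an estimated correlation). The proliferation marker Mki67 was at 54.3%, topoisomerase gene Top2a at 54.4% and the cytokinesis gene Anln at 55.4% of Ad-GFP. Of 36 DNA replication and G1/S genes 28 fell and 0 rose (30 and 1 when adjusted over the list alone), with a median log2 fold change of -0.40 (camera adjusted p = 5.059e-11; adjusted p = 0.00630 with an estimated correlation). The replicative helicase genes Mcm6 and Mcm4 were at 61.8% and 64.2%, and the ribonucleotide reductase gene Rrm1 at 67.0%. Endothelial markers (14 of 15) and macrophage and leukocyte markers (13 of 16) fell in the same samples. Which cells the proliferation transcripts came from was not determined here.

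Genes of antigen presentation fell: 14 of 21, with 0 rising (15 and 0 when adjusted over the list alone; median log2 fold change -0.30; camera adjusted p = 1.618e-05; adjusted p = 0.0328 with an estimated correlation). B2m, the light chain of MHC class I, was at 68.6% of Ad-GFP, H2-D1 at 84.5% and H2-Q6 at 29.2%. The falling members also include Cd74, H2-Aa, H2-Ab1 and H2-Eb1 of the MHC class II pathway, which leukocytes express, with Cd74 at a log2 fold change of -0.55 ± 0.10 (SE, n = 4 per group). Macrophage and leukocyte markers fell in the same samples, 13 of 16, with a median log2 fold change of -0.44 (camera adjusted p = 1.618e-05; adjusted p = 0.167 with an estimated correlation). The type I interferon list was mixed, with 4 rising and 16 falling of 35 (camera adjusted p = 0.112), and Ifit3 rose to 188.9%. Among inflammatory cytokine and chemokine genes 8 rose and 11 fell of 29 (camera adjusted p = 0.479), and Ptgs2, encoding cyclooxygenase-2, fell to 58.3%. Of 28 p53 targets 14 fell and 5 rose (camera adjusted p = 0.0377; adjusted p = 0.237 with an estimated correlation). Pmaip1 was at 68.1%, Plk2 at 83.9% and Sesn2 at 85.0%. The p53 call was lost without Ad-GFP replicate 2 (adjusted p = 0.0565) and without Ad-Cre replicate 1 (adjusted p = 0.0658). The senescence-associated list (3 rose and 8 fell of 22) had a camera adjusted p = 0.118.

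Among metabolic lists, glycolysis genes fell, 13 of 21 with 2 rising (median log2 fold change -0.18; camera adjusted p = 5.883e-07; adjusted p = 0.132 with an estimated correlation). The phosphofructokinase gene Pfkp was at 57.0%, Ldha at 78.7% and Gapdh at 81.9%. Of 24 cholesterol synthesis and uptake genes 15 rose and 1 fell (median log2 fold change 0.20; camera adjusted p = 0.000215; adjusted p = 0.615 with an estimated correlation and 0.0951 under fry). Hsd17b7 was at 134.3%, the squalene synthase gene Fdft1 at 128.1% and the transcription factor gene Srebf2 at 116.3%. Of 23 NRF2 and redox genes 16 fell and 5 rose (median log2 fold change -0.19; camera adjusted p = 0.00183; adjusted p = 0.0991 with an estimated correlation). The member of smallest p, Gpx3, rose to 188.3%, whereas Ucp2 fell to 73.4% and the catalase gene Cat to 77.8%. Nuclear-encoded oxidative phosphorylation (3 rose and 6 fell of 33; camera adjusted p = 0.802; Cox6c rose to 117.7%), the unfolded protein and amino acid response (7 rose and 9 fell of 29; adjusted p = 0.617; Shmt2 fell to 76.8%) and hypoxia (2 rose and 3 fell of 16; adjusted p = 0.802; Hif1a fell to 88.3%) were not called by camera.

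The list of H3K9 methylation and heterochromatin proteins, to which Suv39h1 belongs, had 12 rises and 6 falls among 33 genes (camera adjusted p = 0.374), and Dnmt3a rose to 129.2%. Among 20 tested genes next to Suv39h1 on the X chromosome 3 rose and 3 fell (camera adjusted p = 0.802). Slc35a2, in that neighbourhood, fell to 77.0%. Of 30 germline genes 3 had enough counts to be tested, and none of the 3 changed by edgeR's test.

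**Figure D2:**
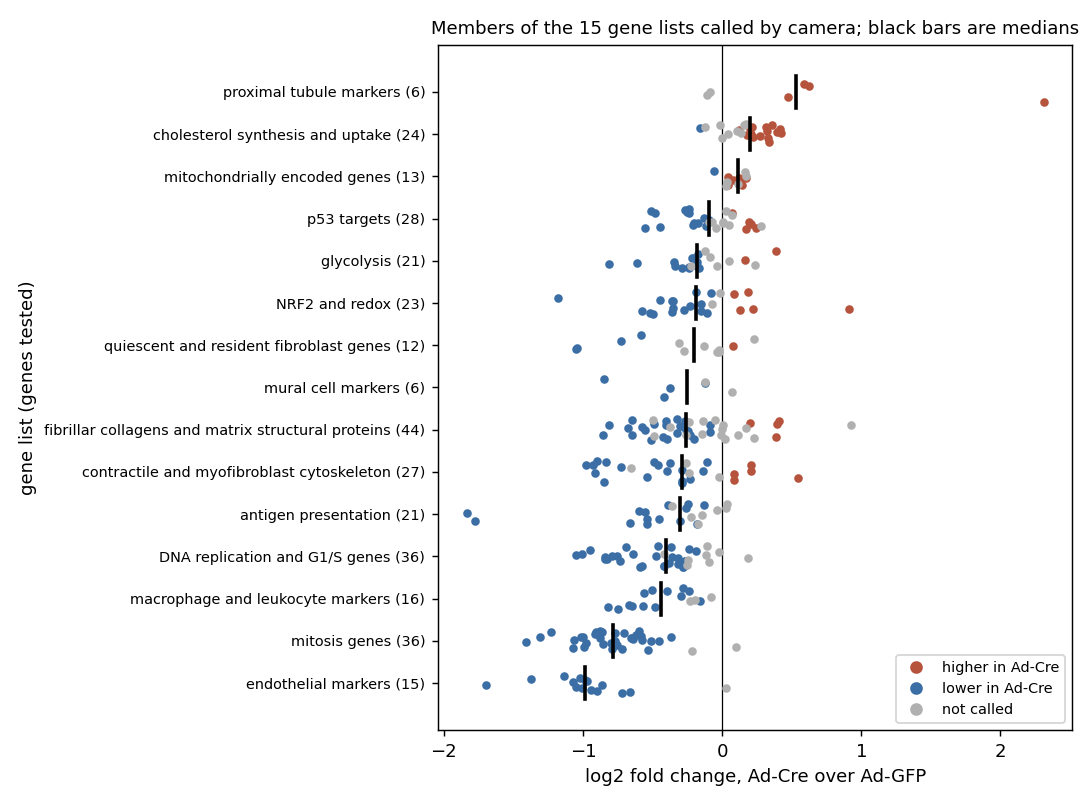
Log2 fold change (Ad-Cre over Ad-GFP) of each tested member of the 15 gene lists called by camera, coloured by the edgeR call (adjusted p under 0.05), with the list median as a black bar and the number of genes tested in parentheses. Medians run from -0.98 for endothelial markers to 0.53 for proximal tubule markers.

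Camera called the endothelial, macrophage, mural and proximal tubule marker lists, of which the endothelial list kept its call with an estimated correlation, and did not call the general epithelial, distal nephron or podocyte lists. Endothelial markers were close to 50% of their Ad-GFP level: 14 of 15 fell and 0 rose (14 and 0 when adjusted over the list alone), with a median log2 fold change of -0.98 (camera adjusted p = 5.059e-11; adjusted p = 0.0229 with an estimated correlation). The VE-cadherin gene Cdh5 dropped from 39.4 ± 1.5 to 19.0 ± 1.6 CPM and Pecam1 from 24.1 ± 1.7 to 12.0 ± 0.5 CPM (SD, n = 4). Of 16 macrophage and leukocyte markers 13 fell and 0 rose, with a median log2 fold change of -0.44 (camera adjusted p = 1.618e-05; adjusted p = 0.167 with an estimated correlation). Its most abundant genes moved less, Lyz2 to 89.5% and Csf1r to 82.5%. Of 6 mural cell markers 4 fell (camera adjusted p = 0.0227; adjusted p = 0.132 with an estimated correlation), and Mcam was at 91.7%. Des and Myh11, shared with the contractile list, are among these falls. Resident fibroblast genes had 4 falls and 1 rise among 12 (camera adjusted p = 0.0229; adjusted p = 0.132 with an estimated correlation). Cd34 was at 48.6% and Igf1 at 66.7%. Cd34 is also expressed by endothelial cells.

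Epithelial transcripts were abundant in both groups. The 18 general epithelial markers summed to 6876 CPM in Ad-GFP and 6374 CPM in Ad-Cre, and 8 rose and 7 fell (camera adjusted p = 0.802). Krt8 fell from 1504 ± 37 to 1168 ± 18 CPM. Of 6 tested proximal tubule markers 4 rose and 0 fell, with a median log2 fold change of 0.53 (camera adjusted p = 0.00426; adjusted p = 0.174 with an estimated correlation). Ggt1 was at 150.0% and the injury marker Havcr1 at 154.4% of Ad-GFP. Distal nephron and collecting duct markers (2 rose and 3 fell of 9) and podocyte and parietal markers (2 rose and 4 fell of 9) were not called, each with a camera adjusted p = 0.802, and Podxl was at 82.9%. Of 3 tested adipocyte and glial markers 1 rose and 1 fell, and Fabp4 was at 54.0%. Immediate early genes had 5 rises and 2 falls among 18 (camera adjusted p = 0.374; Klf6 at 104.8%). Mitochondrially encoded genes had 7 rises and 1 fall among 13 (median log2 fold change 0.12; camera adjusted p = 0.0186; adjusted p = 0.615 with an estimated correlation), and that call was lost without Ad-GFP replicate 2 (adjusted p = 0.0508) and without Ad-Cre replicate 2 (adjusted p = 0.0651), as well as with the filter of at least 5 CPM (adjusted p = 0.0756) and under fry (adjusted p = 0.0951).

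Annotation terms gave gene groups beyond the fixed lists. Among genes lower in Ad-Cre, the KEGG pathway of smallest p was dilated cardiomyopathy (35 of 65 genes; Fisher's exact adjusted p = 3.004e-05), led by the cytoskeletal actin genes Actg1 and Actb and the adenylate cyclase gene Adcy1. Cell adhesion molecules (43 of 95 genes, led by Alcam, Cdh5 and Pecam1; adjusted p = 0.000192) followed. In these pathways 10 and 15 genes were called higher, and 22.82% of all tested genes with a KEGG pathway were called lower. The Gene Ontology processes of smallest p were angiogenesis (83 of 212 genes, including Cav1 and Adam8) and cell adhesion (123 of 358 genes, including Kitl and Itga5), both with an adjusted p = 1.191e-06. In these processes 35 and 70 genes were called higher, and 20.57% of all tested genes with a process term were called lower. The endothelial marker list, which includes Cdh5 and Pecam1, fell in the same samples with a median log2 fold change of -0.98. Among genes higher in Ad-Cre, the KEGG pathways were protein processing in the endoplasmic reticulum (55 of 156 genes, including Nfe2l2 and Sec63; adjusted p = 0.000489), degradation of branched-chain amino acids (22 of 46, including Mmut and Acadsb; adjusted p = 0.00115) and ribosome (46 of 129 genes, including Rplp0; adjusted p = 0.00136). In these pathways 21, 5 and 6 genes were called lower, and 20.35% of all tested genes with a KEGG pathway were called higher. Smoothened signalling was the leading process (28 of 59 genes, including Smo; adjusted p = 0.000608), with 4 genes called lower and a background share called higher of 19.86%. Rplp0 was at a log2 fold change of 0.14 ± 0.018, Smo at 0.25 ± 0.033 and Mmut at 0.48 ± 0.048 (SE, n = 4 per group). With calls limited to at least 2-fold, 19 terms passed in place of 226, all among lower genes. Fisher's exact test takes genes as independent, and no correlation between genes was allowed for in the terms. Their adjusted p-values can therefore be too small, and a term call alone is weak evidence.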

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

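The tests on the wider endothelial panel, the mesenchymal panel, the core TGF-β targets, the endothelial against macrophage comparison, the replication list and the gene length of Suv39h1 were chosen only after the results were seen. The thinning alternative was also added after the library totals were seen.

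Of 274 groups of 4 libraries tested for a single distant sample, 5 had 1 library whose gap to the nearest of the others, divided by the group's whole range, passed Dixon's 95% critical value, which chance passes in about 1 in 20 groups. Suv39h2 was at 7.19 CPM in Ad-Cre replicate 2 against 8.32 to 8.39 in the others (gap over range 0.934). Cyp4b1 was at 6.43 CPM in Ad-Cre replicate 2 against 7.93 to 8.23 (0.835). Slc34a2 was at 28.2 CPM in Ad-Cre replicate 1 against 25.4 to 25.7 (0.906). Mcam was at 143.6 CPM in Ad-GFP replicate 1 against 150.4 to 151.2 (0.895). Epcam, chosen after its values were seen, was at 286 CPM in Ad-GFP replicate 2 against 272.4 to 274.3 (0.861).

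The level of 79.6% left for Suv39h1 is high for a depleted gene. After thinning, the log2 fold change was -0.326 (edgeR adjusted p = 5.47e-05), so the call did not rest on the extra Ad-Cre counts. Thinning leaves the expected ratio as it was, so it cannot test depth as a cause of the ratio. Suv39h1 falls within the middle 90% of the DNA replication list (-0.96 to -0.08, at its 58.3 percentile). That range is wide, and a fall from another cause could lie in it too. Whether a smaller share of dividing cells accounts for the fall is therefore not decided. Transcripts that lack part of the gene stay open: the implied length was 2.91 ± 0.02 kb in Ad-GFP and 2.80 ± 0.03 kb in Ad-Cre without overlap, a shift at the 84.7 percentile of 4286 genes of like count. The bound first written, the 95th percentile, would have counted that shift against this explanation, but it was set aside after the value was seen, because an implied length changes only if the authors' gene models hold the shorter form, and no values per exon were analysed here.

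Endothelial markers fell to about 50% of Ad-GFP. Thinning left the list median at -0.96 (camera adjusted p = 9.269e-11), so the call did not rest on the extra Ad-Cre counts. Because thinning leaves expected ratios as they were, it cannot test depth as a cause of the median. The endothelial and macrophage lists differed (permutation p = 0.00144, two-sided, over genes, which are not independent), in a comparison chosen after both medians were seen. Listed genes that the remaining cells also express would fall less. The difference therefore does not decide on a common loss of all non-epithelial cells. A smaller share of endothelial cells in the Ad-Cre samples is a candidate explanation: a further panel of 30 tested endothelial genes had a median of -1.007 (95% bootstrap interval -1.13 to -0.83) and 26 of the 30 fell. The labels name renal fibroblasts alone and no sort, and lower expression in the same number of endothelial cells was not separated from a lower share.

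Contractile and matrix genes fell with a median of -0.285 over both lists. Thinning left the contractile median at -0.295 (camera adjusted p = 2.294e-10). Without thinning, camera with an estimated correlation called neither the contractile list (adjusted p = 0.0696) nor the matrix list (adjusted p = 0.171). Whether the TGF-β response as a whole was weaker is not decided. A set of 8 core targets had a median of 0.046 (95% bootstrap interval -0.13 to 0.15). These were picked from the fixed TGF-β list after the results were seen, so they cannot stand for the whole response. The whole list had a median of -0.02 and was not called by camera (adjusted p = 0.802), but fry called it lower (adjusted p = 0.0329). A smaller share of mesenchymal cells cannot be told apart from lower expression per cell, since a panel of 30 tested mesenchymal genes had a median of -0.247 with an interval of -0.39 to -0.13 that reaches both the lists' median and values above 50% of it. An effect of Suv39h1 on these genes, which the design names, stays open and untested, as does an effect of Cre itself, because the design has no Cre-expressing sample with intact Suv39h1.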

How the results depend on the processing

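Suv39h1 stayed lower and called in every alternative, with log2 fold changes of -0.265 to -0.35 over those with all libraries and -0.303 to -0.372 on leaving out 1 library. Leaving out 1 library gave 4818 to 5076 changed genes and 259 to 280 changed at least 2-fold. Limma on log2(FPKM + 1) gave 3530 changed genes (1400 higher) and on log2(FPKM + 0.1) 3520 (1393 higher). Fewer genes were tested there (11679), which does not account for the whole drop, and the rest of the cause was not tested. Counts of at least 2-fold were 435 (58 higher, 377 lower) with no filter, 56 (4 and 52) with at least 5 CPM, 28 (2 and 26) with log2(FPKM + 1) and 90 (4 and 86) with log2(FPKM + 0.1). The filters act by adding or removing low genes, and a larger pseudocount shrinks the folds of low genes. Camera called 4 lists with an estimated correlation and 13 to 15 on leaving out 1 library, and with calls of at least 2-fold 19 annotation terms passed, where fewer genes enter. Of 2519 values of named genes under the alternatives, 25 lost a call, 13 gained one and 0 reversed. Of 448 for lists, 18 lost a call, 8 gained one, all under fry, and 0 reversed. The labels state no pairing by replicate number. Correlations between the groups ran from 0.026 to 0.166 for libraries of the same number and from -0.171 to 0.082 for the others. In each group 3 of 4 libraries correlated best with their own number, a hint of pairing from the data only. With the replicate block, 5390 genes changed, 262 at least 2-fold, 15 lists and 262 terms passed, and Suv39h1 was at -0.328. Upper-quartile factors gave 2164 higher and 3089 lower genes (41.2% higher, against 49.2%). Thinning every library to 15879244 counts, an alternative added after the library totals were seen, gave 5048 changed genes and 259 changed at least 2-fold.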

Other observations

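The test by other splits of the samples was planned, and the genes of the first 2 paragraphs were chosen after their values were seen.

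Type IV collagen chains moved apart. Col4a1 and Col4a2, which form the ubiquitous basement membrane network, fell from 618.8 ± 12.9 to 495.1 ± 12.2 CPM and from 346.9 ± 4.0 to 295.4 ± 8.3 CPM (SD, n = 4). Col4a3 and Col4a4, chains of the network of the mature glomerular basement membrane, rose from 568.7 ± 10.99 to 893.6 ± 7.3 CPM and from 364.1 ± 12.4 to 459.4 ± 4.9 CPM. Their partner Col4a5 was at 189.5 ± 4.6 and 180.1 ± 2.4 CPM, a small fall whose call was lost without Ad-GFP replicate 2, Ad-GFP replicate 4 or Ad-Cre replicate 2.

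Transcripts of both epithelial and fibroblast marker lists were present in both groups. The 12 tested members of the fixed resident fibroblast list summed to 1467 CPM in Ad-GFP and 1440 CPM in Ad-Cre. The 18 general epithelial markers summed to 6876 and 6374 CPM. A few abundant genes can set such sums. Over the 8 libraries, the median was 12.67 CPM for the fibroblast list, of which 12 of 22 genes were tested. It was 186.6 CPM for the epithelial list. Cdh1 was at 700.2 ± 17.1 CPM in Ad-GFP and 677.0 ± 7.0 in Ad-Cre, and Epcam rose from 276.5 ± 6.4 to 326.2 ± 3.4 CPM. Pdgfra was at 5.14 ± 0.46 and 4.24 ± 0.50 CPM, Pdgfrb at 27.96 ± 1.89 and 25.5 ± 1.3 CPM, and Dcn at 4.19 ± 0.56 and 4.81 ± 2.23 CPM. Thy1, a surface marker of fibroblasts, fell from 7.19 ± 0.43 to 1.54 ± 0.42 CPM.

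Random grouping of these libraries is excluded as the source of the counts of changed genes only as far as 35 splits allow. Of the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave 5370 changed genes and 256 changed at least 2-fold, and the highest other split gave 0 of each. Every other split carries part of the group difference as spread within its groups, which favours a count of 0. Permuting libraries does not exclude a chance difference between the cultures behind the groups. For gene lists, 1 of the 35 splits gave 15 calls, again the real one, and the highest other gave 14. The 16 splits that keep 3 libraries of a group together gave 9 to 14 list calls, and the 18 splits that mix the groups evenly gave 0 to 5. Camera with its preset correlation thus calls some lists with no group difference, and a list call alone is weak evidence here.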
